A study of Homo sapiens with 8 samples.

How the data were processed

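Poly(A) RNA of H1 human embryonic stem cells was sequenced after transduction with GFP-marked lentivirus carrying a control shRNA or an shRNA against NAT10; per the labels' protocols, cells were cultured for 48 h, GFP-positive cells were enriched, and these were expanded with 0.5 ug/ml puromycin. Libraries were DNA nanoballs read on a BGISEQ platform, per the labels' protocols. Groups and replicate numbers came from the sample titles, 4 libraries per group.

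Per the submitters' processing notes, which name tools without their order, fastp 0.21.1, HISAT2 2.2.1, SAMtools 1.12, featureCounts 2.0.3 and DESeq2 1.26.0 were used with the hg38 build. The gene annotation and the strand setting are not given in the sources used here. The deposited values are a signal: read counts per gene divided by a size factor per library, although the columns are named as read counts. In every library 100% of values were whole multiples of a constant step within 1e-06 of a read, and the factors obtained from these steps, between 0.971 and 1.04, equalled median-of-ratios size factors recomputed from the genes of the table with differences of at most 1.11e-16. Every gene had at least 10 reads in at least 4 libraries, so genes below that level were not analysed here. Dividing by size factors assumes that most genes do not change, and low filtering thresholds in the deposited table fix which genes could be tested.

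The design set at the start assumed raw counts and edgeR. Because the deposited unit is a normalized signal, the main test was limma 3.58.1 (trended, robust empirical Bayes) in R 4.3.3 on log2(value + 1), with group as the only term and Benjamini-Hochberg adjustment over 17546 genes at 0.05. Fold changes are on this log2(value + 1) scale, which understates changes of genes with few reads. That edgeR 4.0.16 quasi-likelihood test on the recovered reads, with TMM and 17410 genes kept by its filter, called 5556 genes up and 5795 down, and 11195 of these were called in the same direction by limma. The biological coefficient of variation was 3.33%. Single library values were compared by two-sided exact permutation tests.

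Gene lists, 31 in number, were fixed at the start and 30 had at least 2 measured members. They were tested with camera at a preset correlation of 0.01, with adjustment over the lists, and again with an estimated correlation and with fry, which asks only whether a list's genes move one way on balance. The genes named were fixed by rule: NAT10; the 8 largest increases and 8 largest decreases among genes with an official symbol, an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between groups; POU5F1, SOX2, NANOG, ANP32B and THUMPD1; and the 2 members of each list with the smallest adjusted p, 4 for pluripotency. XIST, Y-linked and small RNA genes were left out. Coordinates and gene types came from GENCODE release 29 on GRCh38, the same build as hg38, matched by Ensembl gene ID; 17225 of 17546 IDs had an entry there and 17532 had a symbol.

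Replicates were compared before averaging. Chi-square per gene between pairs of libraries was 1.79 to 2.52 within groups and 28.1 to 29.1 between groups. Each library counted as its own sample, as titled. These values cannot show whether the replicates came from separate cultures. With 15574631 to 16305014 reads per library, a count of 0 allows up to 0.193 CPM in the shallowest library (3 counts of its total, counting error only).

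The tests were tested on simulated data drawn from the control means, the library totals and the estimated dispersions for all 17546 genes. For this comparison limma recovered 21, 39, 47 and 50 of 50 genes changed 1.25-, 1.5-, 2- and 4-fold and called 5 unchanged genes. Camera called 5 of 5 lists changed 1.25-fold and 0 of 20 unchanged lists. Genes were drawn independently, so the simulation cannot show how camera at the preset correlation behaves when list members vary together. Few genes were changed in it, against 64.7% called in the real data, so its recovery need not carry over. Alternatives chosen before the data were examined were other scalings, DESeq2 1.42.0, limma-voom, low-count filters, a replicate block, leaving out each library, leaving out mitochondrial genes and stricter thresholds. Pseudocounts of 0.5 and 5 and limma with TMM factors or (for genes) with library totals were chosen after seeing the data. So was limma as the main test. The edgeR test with TMM was set at the start, and only its use on recovered reads as an alternative came later. Figures were drawn with matplotlib 3.10.9.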

Results

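RNA was measured in H1 cells, a human embryonic stem cell line, that had been transduced with lentivirus carrying either a negative control shRNA or an shRNA against NAT10, the enzyme that places N4-acetylcytidine (ac4C) on RNA. The 8 poly(A)-selected libraries fell into 2 groups of 4, control shRNA and NAT10 knockdown, and covered 17546 genes. Recovered read totals ran from 15574631 to 16305014 per library, 15.9 ± 0.227 M reads in controls and 16.3 ± 0.0402 M reads in knockdown (mean ± SD, n = 4 each, two-sided exact permutation p = 0.0286, the smallest p that 4 against 4 can give). After the authors' scaling the totals were 15.4 ± 0.0786 M and 16.6 ± 0.0589 M (exact permutation p = 0.0286, n = 4 each). Genes of the mitochondrial chromosome took 10.1% ± 0.118 of the signal in controls and 10.2% ± 0.244 in knockdown (exact permutation p = 0.257, n = 4 each). The labels do not say whether the 4 replicates of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

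The comparison between the groups asked which transcripts differ between human embryonic stem cells given the NAT10 shRNA and those given the control shRNA. No rescue group was among the samples. Effects of lower NAT10 therefore cannot be told apart from off-target effects of the shRNA or from other differences between the cell populations. NAT10 itself fell to 74.7% of the control level. Cells of the knockdown group carried more RNA of the annexin ANXA1, of the Nodal antagonists CER1 and LEFTY2, and of the cytoskeletal and caveolar genes FLNC, TAGLN and CAV1. They carried less RNA of the metallothioneins MT1E, MT1H, MT1G and MT2A, of the cell cycle inhibitor CDKN1A and of the ERK phosphatase DUSP6. Among the gene groups, cholesterol synthesis, ribosome biogenesis, pluripotency, unfolded protein response and DNA replication genes rose, and mitotic genes fell. Reference genes, listed as a check of the scaling, leaned upward too (7 of 11 up, 1 down). Their median log2 fold change was 0.24, against 0.20 for DNA replication, so rises of that size are not set apart from genes of even expression.

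NAT10 (ENSG00000135372, hg38 chromosome 11, 34105602 to 34147670, plus strand) had 2207, 2285, 2048 and 2173 normalized counts in control replicates 1 to 4 and 1647, 1592, 1625 and 1644 in knockdown replicates 1 to 4. The means were 2178 ± 98.8 and 1627 ± 25.5 (SD, n = 4 each), a decrease of 25.3% with no overlap between the groups (two-sided exact permutation p = 0.0286). On the log2(value + 1) scale the change was -0.42 with a standard error of 0.0378 (adjusted p = 5.88e-14).

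**Figure D1:**
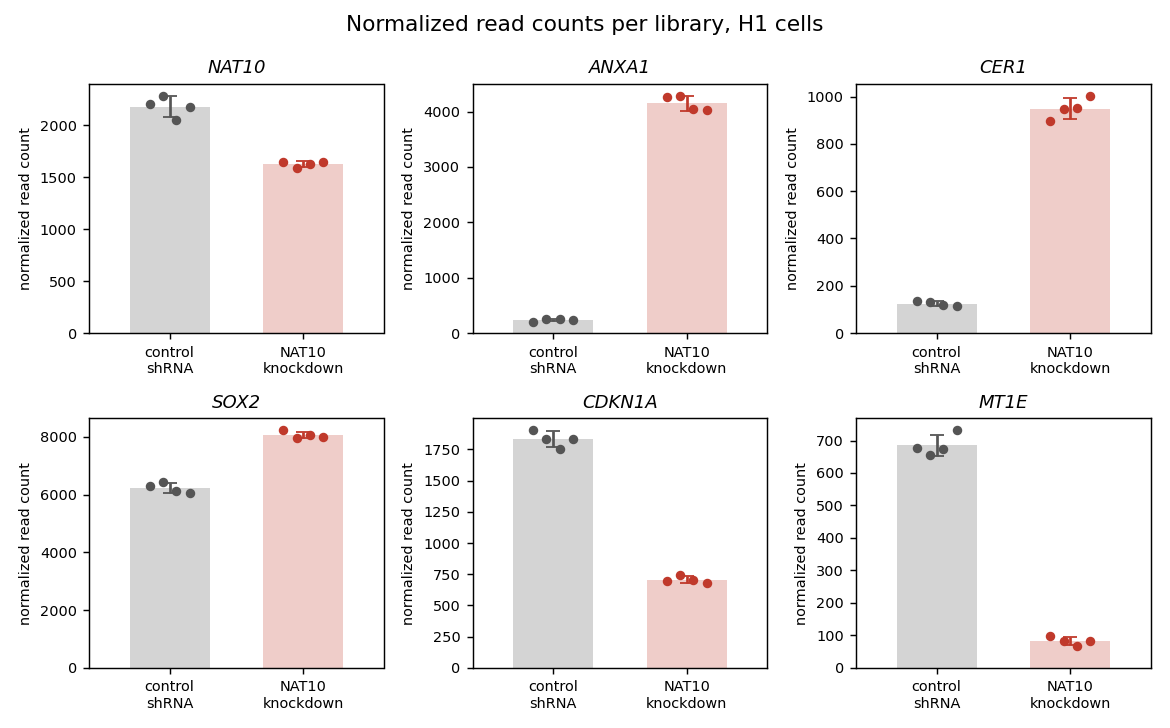
Normalized read counts of NAT10, ANXA1, CER1, SOX2, CDKN1A and MT1E in each of the 8 libraries (vertical axes, linear from 0; points are libraries, bars are group means and error bars are SD, n = 4). NAT10, CDKN1A and MT1E were lower in every knockdown library than in any control library, and ANXA1, CER1 and SOX2 were higher.

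Of the 17546 genes, 5667 rose and 5680 fell at an adjusted p under 0.05, 64.7% of those tested. With the library totals alone as scaling, the median of all genes moved by -0.11 on the log2 scale and the split became 4079 higher and 7349 lower, or 35.7% higher against 49.9% with the authors' scaling, so directions are relative to that scaling. Most changes were small: the median fold of the changed genes was 1.36, and 7123 of them (62.8%) changed by less than 1.5-fold. A change of at least 2-fold was found for 590 raised and 1093 lowered genes, of which 415 and 692 were protein-coding, and 88 rose and 112 fell at least 4-fold. Restricted to the 11690 genes with a mean of at least 5 CPM, the 2-fold counts were 227 raised and 279 lowered. The groups did not overlap for 9948 genes (56.7%), where chance gives 2.86%.

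The 8 largest increases among genes of at least 5 CPM were in ANXA1, MFAP5, AADACL3, SERPINB9, FAM20A, CER1, CAV1 and FLNC. ANXA1, a calcium-dependent phospholipid-binding protein (chromosome 9, 73151757 to 73170393), went from 236 ± 25.1 to 4154 ± 135 normalized counts, a log2 fold change of 4.14. MFAP5, a component of extracellular microfibrils, rose from 16.2 ± 2.11 to 275 ± 35.3 counts, and AADACL3 rose to 159 ± 8.03 counts (log2 fold change 3.32). SERPINB9, an inhibitor of granzyme B, rose from 1010 ± 26.0 to 8175 ± 303 counts (log2 fold change 3.02). FAM20A rose from 38.3 ± 7.56 to 308 ± 5.38 counts and CER1 from 125 ± 9.80 to 949 ± 44.7. CAV1, the main structural protein of caveolae, rose by 2.79 and FLNC, an actin cross-linking filamin, by 2.72 on the log2 scale. Adjusted p-values of these 8 genes lay between 3.98e-51 for SERPINB9 and 1.84e-25 for AADACL3.

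The 8 largest decreases were in CTCFL, MT1E, MT1H, MVP, MT1G, MT2A, SULF1 and TXNIP. CTCFL, a paralog of the insulator protein CTCF (chromosome 20, 57495966 to 57525652), went from 342 ± 21.1 to 39.6 ± 5.31 normalized counts, a log2 fold change of -3.08. The metallothioneins, small cysteine-rich proteins that bind zinc and copper, lie together on chromosome 16, where MT2A starts at 56608199 and MT1H ends at 56671129. MT1E changed by -3.05, MT1H by -2.98, MT1G by -2.53 and MT2A by -2.49 on the log2 scale. These genes are near-identical paralogs, so the split of reads among them is uncertain. MVP, the major vault protein, changed by -2.56, the sulfatase SULF1 by -2.30 and TXNIP, a thioredoxin-binding protein induced by glucose, by -2.17. Adjusted p-values lay between 5.06e-34 for MT1E and 1.58e-06 for MT1G.

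Of 29 measured pluripotency genes, 19 rose, 3 fell and 7 did not pass the test, with the same counts adjusted over the list alone (median log2 fold change 0.31, camera adjusted p = 1.87e-05, and 0.0278 with an estimated correlation). With library totals 17 of them rose and 9 fell, with a median of 0.20. PRDM14, a repressor of differentiation genes, rose from 414 ± 22.0 to 1540 ± 51.6 normalized counts (log2 fold change 1.90). FGF2 rose by 0.81, the let-7 inhibitor LIN28B by 0.80, UTF1 by 0.90 and the core factor SOX2 by 0.37 on the log2 scale. NANOG had 543 ± 33.4 counts in controls and 569 ± 32.2 in knockdown (log2 fold change 0.067, adjusted p = 0.286). POU5F1 was counted at only 24.0 ± 5.63 and 17.2 ± 7.11 (log2 fold change -0.50, adjusted p = 0.0642), far below the other core factors; the assembly holds further copies of its locus, and its processed pseudogene POU5F1P3 was counted at 2332 ± 76.2 and 2294 ± 89.3. Without control replicate 2 its change was -0.58 (adjusted p = 0.0494) and without knockdown replicate 1 it was -0.75 (adjusted p = 0.00848), and its adjusted p ranged from 0.00848 to 0.241 over 20 alternatives. Among the 8 measured genes of naive pluripotency, 5 rose and 2 fell, as they did adjusted over the list alone, with ALPG up by 1.80 and TFCP2L1 changed by -0.69 (camera adjusted p = 0.422).

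Markers of other lineages moved in both directions and few were measured. In neuroectoderm 8 of 13 measured genes rose and 3 fell, NES by 1.15 and the neural cadherin CDH2 by 1.29 among those that rose, but the list did not pass (camera adjusted p = 0.0851); with library totals it did (8 up, 5 down, adjusted p = 0.0408), and over 15 alternatives its adjusted p ranged up to 0.608. Of 6 measured definitive endoderm genes 3 rose, with AFP up by 1.93 and CER1 by 2.92, and 2 fell (camera adjusted p = 0.270). Of 8 trophoblast and amnion genes 5 rose, with BMP4 up by 2.05 and IGFBP3 by 1.35, and 2 fell (camera adjusted p = 0.105). In neural crest 3 of 9 rose, FOXD3 from 263 ± 22.5 to 629 ± 44.4 counts, and 4 fell, with NGFR changed by -1.99 (camera adjusted p = 0.914, direction down with a mean of -0.097 although the median was 0.018). Of 7 primitive streak and mesoderm genes 3 rose and 3 fell, with FGF8 up by 2.14 and TBX6 changed by -0.97 (camera adjusted p = 0.921, direction up although the median was -0.047 and the mean -0.088). Counts for these 5 lists were the same adjusted over the list alone. With library totals definitive endoderm counted 2 up and 2 down, and primitive streak and mesoderm 3 up and 4 down. Of the 39 HOX genes, 0 were among the genes of the table used here.

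Of 13 measured fibroblast and mesenchymal markers, 9 rose and 1 fell, also adjusted over the list alone (median 0.24, camera adjusted p = 0.00244; adjusted p = 0.240 with an estimated correlation). With library totals 6 of them rose and 2 fell, with a median of 0.13. TAGLN, an actin-binding protein of contractile cells, rose from 1422 ± 81.6 to 5689 ± 273 counts, and the intermediate filament gene VIM by 1.67. Among 16 Nodal and TGF-beta targets 9 rose and 3 fell, also adjusted over the list alone (median 0.16, camera adjusted p = 0.0216; adjusted p = 0.129 with an estimated correlation). LEFTY2 rose from 666 ± 20.9 to 3491 ± 143 counts (log2 fold change 2.39). With library totals 8 of the 16 rose and 6 fell, with a median of 0.050. The call of this list was lost among genes of at least 5 CPM (adjusted p = 0.168, from 0.0119 to 0.168 over 15 alternatives). FGF and ERK targets (4 of 15 up, 7 down) and WNT targets (3 of 10 up, 3 down) did not pass (camera adjusted p = 0.105 and 0.504), with the same counts adjusted over the list alone; with library totals WNT targets counted 2 up and 5 down. The 2 members of each with the smallest adjusted p were lower: the ERK feedback inhibitors DUSP6 changed by -1.60 and SPRY4 by -0.77, NKD1 by -1.44 and SP8 by -1.15. Of 23 basement membrane and adhesion genes 10 rose and 9 fell, also adjusted over the list alone (camera adjusted p = 0.876), or 7 and 12 with library totals, with ITGAV up by 0.79 and FREM2 changed by -0.90.

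Genes of ribosome biogenesis, a nucleolar process in which NAT10 acts, rose. Of 63 measured ribosome biogenesis genes, 52 rose and 2 fell, also adjusted over the list alone (median 0.32, camera adjusted p = 1.24e-11, and 0.0132 with an estimated correlation). UTP14A, a component of the small-subunit processome, rose from 341 ± 21.9 to 824 ± 32.5 counts (log2 fold change 1.27), and UBTF, a transcription factor of RNA polymerase I, from 1549.8 ± 23.5 to 3161 ± 164 counts. Of 75 ribosomal protein genes 34 rose and 2 fell, or 33 and 1 adjusted over the list alone, by small amounts: RPL22 by 0.32 and RPS27A by 0.29 (list median 0.12, camera adjusted p = 0.000854; adjusted p = 0.517 with an estimated correlation). With library totals 8 of them rose and 13 fell, with a median of 0.013 (adjusted p = 0.183, the highest of 15 alternatives, which began at 3.58e-05), and the list also passed in 10 of 18 splits that put 2 libraries of each group on either side. Of 14 snoRNA host genes 8 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.0851), SNHG7 by 0.80 and SNHG12 by 0.50; with library totals 5 rose and 5 fell, and without knockdown replicate 4 this list passed (adjusted p = 0.0445, and up to 0.224 over 15 alternatives).

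Of 37 genes listed as writers, erasers or readers of RNA modifications, NAT10 left out, 21 rose and 8 fell, also adjusted over the list alone (median 0.14, camera adjusted p = 0.0128; adjusted p = 0.164 with an estimated correlation). NSUN2, which places 5-methylcytosine on RNA, rose by 0.56, and DNMT3A by 0.67; DNMT3A is a DNA methyltransferase, although the list held it. The call was lost with library totals (16 up, 11 down, median 0.034, adjusted p = 0.0613) and among genes of at least 5 CPM (adjusted p = 0.0809), the highest of 15 alternatives that began at 0.00899. The tRNA acetylation partner THUMPD1 had 1082 ± 21.1 and 1107 ± 32.3 counts (log2 fold change 0.033, adjusted p = 0.502). ANP32B, a histone chaperone, fell by 0.17 on the log2 scale, from 3210 ± 113 to 2851 ± 176 counts (adjusted p = 9.28e-05). The histone chaperones as a group, 8 of 22 up and 7 down over all genes and adjusted over the list alone, did not pass (camera adjusted p = 0.614) and counted 7 up and 10 down with library totals, with SUPT6H up by 0.67 and CABIN1 changed by -0.45.

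Of 39 chromatin modifiers 21 rose, CREBBP by 0.96, and 9 fell, among them CBX7 with a log2 fold change of -1.25, with the same counts adjusted over the list alone (median 0.14, camera adjusted p = 0.0375; adjusted p = 0.477 with an estimated correlation). The list of chromatin modifiers had an adjusted p of 0.050005 without control replicate 3, 0.0531 without control replicate 4 and 0.0518 without knockdown replicate 4, each above the threshold, and 0.170 with library totals (16 up, 13 down, median 0.030) and 0.199 among genes of at least 5 CPM. Over 15 alternatives it ranged from 0.0260 to 0.199.

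Genes of DNA replication and of mitosis moved in opposite directions. Of 34 replication genes 22 rose and 4 fell, also adjusted over the list alone (median 0.20, camera adjusted p = 0.000448, and 0.0278 with an estimated correlation), with the helicase subunits MCM2 up by 0.79 and MCM5 by 0.57. With library totals 17 of them rose and 8 fell, with a median of 0.090. Both medians lay below those of the reference genes (0.24, and 0.13 with library totals). The rise of the replication genes is therefore not set apart from genes of even expression. Of 30 mitotic genes 22 fell and 1 rose, or 22 and 2 adjusted over the list alone (median -0.32, camera adjusted p = 7.02e-07, and 0.0278 with an estimated correlation). TOP2A, the mitotic topoisomerase, went from 7719 ± 204 to 4507 ± 213 counts (log2 fold change -0.78), and the spindle checkpoint kinase BUB1B changed by -0.78.

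p53 targets fell as a group, with 21 of 29 lower and 5 higher, also adjusted over the list alone (median -0.36, camera adjusted p = 0.000158; adjusted p = 0.0818 with an estimated correlation). CDKN1A, which encodes the cell cycle inhibitor p21, went from 1833 ± 60.8 to 707 ± 28.5 counts (log2 fold change -1.37), and the antiproliferative gene BTG2 changed by -1.62. In the integrated stress response, ATF4 and its targets, 16 of 23 genes fell and 3 rose, also adjusted over the list alone (median -0.23, camera adjusted p = 0.000854; adjusted p = 0.0819 with an estimated correlation). ATF4 itself did not pass (log2 fold change -0.032, adjusted p = 0.379). DDIT4, an inhibitor of mTORC1, changed by -2.16 while the amino acid transporter SLC7A5 rose by 0.83. In hypoxia and glycolysis 16 of 22 genes fell and 3 rose, or 17 and 3 adjusted over the list alone (median -0.24, camera adjusted p = 0.00212; adjusted p = 0.0818 with an estimated correlation), with BNIP3 changed by -1.12 and ADM up by 1.77.

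Of 19 unfolded protein response genes 15 rose and 1 fell, also adjusted over the list alone (median 0.28, camera adjusted p = 4.33e-05, and 0.0436 with an estimated correlation), among them the endoplasmic reticulum chaperones HSPA5, up by 0.80, and CANX, up by 0.65. Cholesterol synthesis genes rose together, 20 of 22 with 0 lower, also adjusted over the list alone (median 0.60, camera adjusted p = 1.24e-11, and 0.00665 with an estimated correlation). HMGCS1, the synthase of HMG-CoA, rose from 5538 ± 126 to 10859 ± 250 counts (log2 fold change 0.97) and ACAT2 by 1.01.

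**Figure D2:**
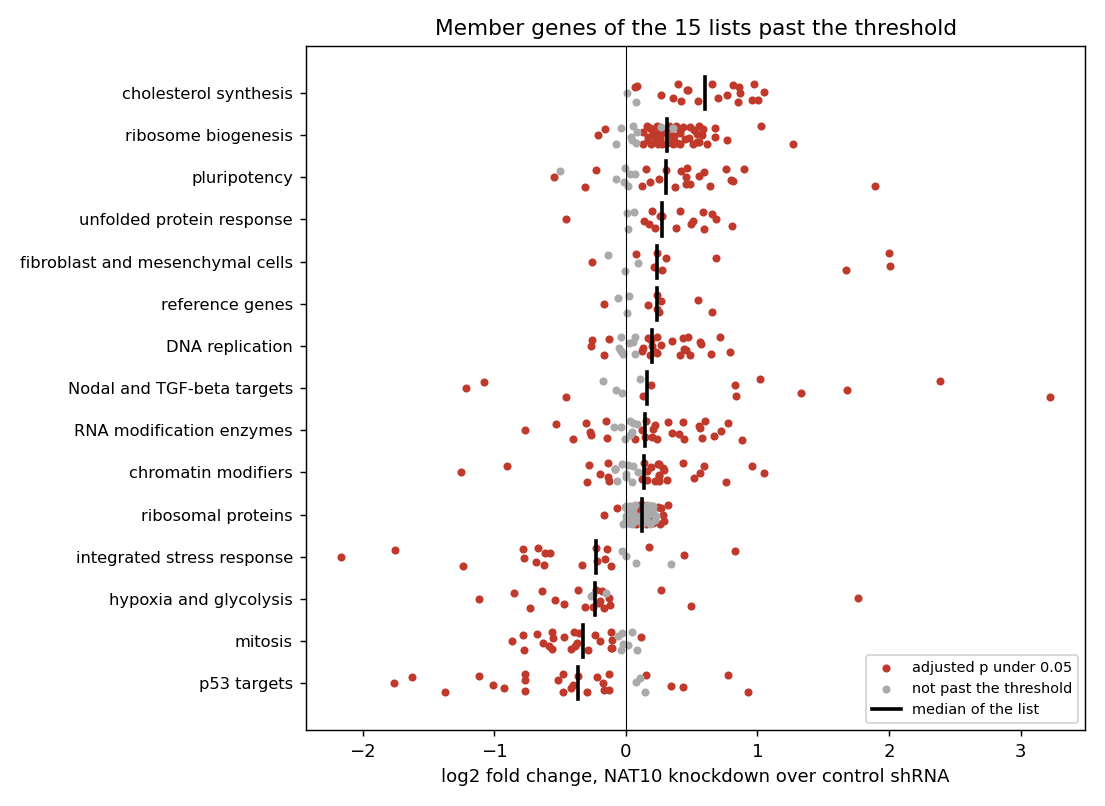
Log2 fold change of each measured member gene (horizontal axis, NAT10 knockdown over control shRNA, 4 libraries each) in the 15 lists past the threshold, with red points for genes at an adjusted p under 0.05, grey points for the others and black lines for list medians. Cholesterol synthesis had the highest median, 0.60, and p53 targets the lowest, -0.36; with library totals the 15 medians kept their signs, but 4 of the lists lost their call and the median of ribosomal proteins became 0.013.

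The remaining lists did not pass, apart from the reference genes. Interferon response genes counted 4 up and 10 down of 21 (camera adjusted p = 0.0851), with DDX60 changed by -1.76 and IFITM1 by -0.44, and passed among genes of at least 5 CPM (adjusted p = 0.0087, and up to 0.171 over 15 alternatives). Immediate early and heat shock genes counted 5 up and 11 down of 20 (camera adjusted p = 0.620), with the constitutive chaperone HSPA8 up by 1.29 and NR4A1 changed by -1.16. Of 38 nuclear OXPHOS genes 11 rose and 4 fell, or 10 and 4 adjusted over the list alone (camera adjusted p = 0.423), but 5 rose and 12 fell with library totals. ATP5PB was up by 0.26 and NDUFB9 by 0.30. Of 13 mitochondrially encoded genes 6 rose and 1 fell, or 3 and 2 with library totals (camera adjusted p = 0.0851 with the authors' scaling), with MT-CYB up by 0.47 and MT-ND4 changed by -0.12. Counts adjusted over the list alone were the same for interferon, immediate early and mitochondrially encoded genes. The 11 reference genes were chosen for even expression across tissues, as a check of the scaling. Of these, 7 rose, SNRPD3 by 0.66 and REEP5 by 0.55, and 1 fell, also adjusted over the list alone. Their median was 0.24 (camera adjusted p = 0.0375, and 0.245 with an estimated correlation). Their adjusted p was 0.050005 without control replicate 3, just above the threshold, 0.159 with library totals (6 up, 4 down, median 0.13) and 0.124 among genes of at least 5 CPM. It ranged from 0.0269 to 0.159 over 15 alternatives.

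In all, 15 of 30 tested lists passed, 11 upward and 4 downward, and 6 of the 15 held with an estimated correlation. Exons of DDIT4, DUSP6, ACAT2, IFITM1, SNHG7, NGFR, VIM, SNRPD3, MCM2, CBX7 and NDUFB9 overlap other annotated genes over 41.2%, 40.5%, 52.3%, 32.5%, 31.4%, 27.1%, 24.4%, 24.6%, 23.6%, 21.6% and 21.0% of their length, and those of HMGCS1, FGF2, TAGLN, ATP5PB, NR4A1, BUB1B and RPL22 over smaller parts, down to 10.1%. Their counts are uncertain because the strand setting is not given in the sources used here. Ribosomal protein, HSPA8 and mitochondrial counts can be shared with pseudogenes.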

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

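The tests of assembly copies, the pluripotent state, pseudogenes, scaling, protein-coding genes, exon number and intronic genes were chosen only after the result was seen, while the counts over splits of the libraries were set at the start.

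In 9 of 174 groups of 4 libraries, 1 library stood apart from the rest by a gap, relative to the group's range, beyond Dixon's 95% critical value; chance alone gives about 8.7. POU5F1 in knockdown replicate 1 had 27.8 normalized counts against 13.2 to 14.3 in the others (ratio 0.926). Control replicate 2 had 15.6 M reads against 16.0 M in each of the others (0.906). Control replicate 1 was high in SNHG12 (520 counts, 0.850) and SLC7A5 (11197, 0.862), and control replicate 4 was high in TAGLN (1543, 0.842) and HSPA8 (20230, 0.837) and low in CANX (6928, 0.843). Knockdown replicate 4 was low in LEFTY2 (3278, 0.859) and high in DUSP6 (1406, 0.863).

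POU5F1, the defining transcription factor of embryonic stem cells, lay at the 16.0th percentile of genes in control libraries. Loss of the pluripotent state is argued against, because the median percentile of the other 28 measured pluripotency genes was 95.03 and the lowest 46.1. Reads lost where the assembly holds further copies of a locus remain a candidate explanation: of 23 genes in 16 housekeeping lists with such a copy, 11 were under 100 normalized counts or absent from the table used here, against 24 of 487 genes without one (two-sided Fisher exact p = 2.40e-08). In the same way, 8 of 181 protein-coding genes in the stretch of chromosome 6 around POU5F1 were in that table (4.42%), against 69.7% elsewhere. Part of its reads may also have been counted at processed pseudogenes, since POU5F1P3 had 2332 ± 76.2 and 2294 ± 89.3 counts (SD, n = 4 each), the 99.9th percentile of 1065 processed pseudogenes, with a log2 fold change of -0.023; the counts of POU5F1 therefore leave the level of its RNA open.

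More genes fell than rose at least 2-fold (1093 against 590), and the excess lay among weakly expressed genes: 652 against 291 among the 4387 genes with the lowest means, 362 against 176 among the next 4386, and 20 against 50 among the 4387 with the highest. Scaling as the whole cause is argued against, because a factor per library moves weakly and strongly expressed genes alike, whereas among the most expressed genes 71.4% of those changed at least 2-fold were raised (95% exact Clopper-Pearson interval 59.4% to 81.6%). A lower output of noncoding genes alone is argued against, because 692 protein-coding genes fell and 415 rose at least 2-fold, 277 of the excess of 503, and the raised share of these was 37.5% (95% exact Clopper-Pearson interval 34.6% to 40.4%). For less RNA from introns or less genomic DNA, 79 sense-intronic genes had a median of -0.018 and 727 lincRNA genes one of -0.36. Sense-intronic genes thus fell less at the median, by a difference of 0.34 (95% interval over resampled genes 0.14 to 0.50). That difference is smaller than the SD of the sense-intronic genes (0.74), which have few reads and went both ways. The test therefore cannot decide, and this explanation stays open. For the noncoding part (293 lowered, 102 raised), less unspliced RNA was examined in genes with 1 exon and with several. Exons were merged over all transcripts of a gene, so a gene counted with 1 exon may still have a spliced transcript. The 448 noncoding genes with 1 exon had a median of -0.24 (95% interval over resampled genes -0.34 to -0.16). The 1387 with several exons had a median of -0.25, a difference of 0.012 (-0.087 to 0.107). Genes with 1 exon thus fell about as far at the median as those with several. Single genes with 1 exon varied widely (SD 0.79), so the test cannot decide, and this explanation stays open. A response to NAT10 knockdown, GC content and gene length also stay open and were not tested.

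Of 35 splits of the 8 libraries into 4 and 4, 1 (the real one) gave 11347 changed genes, and the highest of the others gave 1. Every other split mixes the groups, so the group difference adds to its spread and lowers its count. A share of 1 in 35 is also the smallest these splits can give. They show that the libraries differ by group, and cannot tell an effect of the shRNA from another difference between the groups. For changes of at least 2-fold the real split gave 1683 genes and the highest other 1, and 1 of 35 reached as many. For the lists, 1 of 35 splits gave 15 or more, but the highest other gave 14. That split was among the 16 that exchange 1 library of each group and so carry part of the real difference. Among the 18 that put 2 libraries of each group on either side, the highest was 4. In these 18, ribosomal proteins passed in 10, nuclear OXPHOS genes in 6, snoRNA host genes in 5 and mitochondrially encoded genes in 2. The fibroblast and mesenchymal list and the chromatin modifiers passed in 1 each, and the other lists in 0.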

How the results depend on the processing

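The pseudocounts and limma with TMM factors or (for genes) library totals were chosen after seeing the data, as was limma as the main test. The edgeR test with TMM was set at the start, and its use as an alternative on recovered reads came later. Across all alternatives the counts of changed genes stayed within 1.5 times of the main ones, except when tested against a fold change of 1.5, a stricter question (744 up, 1096 down), and, for changes of at least 2-fold, among the fewer genes with a mean of at least 5 CPM (227 up, 279 down). Lists called numbered 6 with an estimated correlation and 28 with fry, which does not compare a list with other genes. DESeq2 called 5182 genes up and 5139 down. With 1 library left out, 10886 to 11007 genes were called against 11347 with all. NAT10 kept its direction and call under every alternative scaling, filter, gene test and library left out. Its fold change of 0.75 is a smaller change than 1.5-fold, so it could not be called in the test against a fold change of 1.5.

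With library totals, whose construction lowers all fold changes, NANOG became -0.042 and THUMPD1 -0.076 in both limma and edgeR, and the list medians of neural crest (-0.081), histone chaperones (-0.081) and nuclear OXPHOS genes (-0.058) changed sign, and so did the test direction of each; the median of mitochondrially encoded genes also changed sign (-0.010) while its test direction stayed up. With the same totals POU5F1 became a call, at -0.61 with limma and -0.59 with edgeR. Among genes of at least 5 CPM, where fewer genes are tested, the test direction turned for naive pluripotency (median -0.12), neural crest (0.18) and primitive streak (-0.51). The latter's direction also turned without knockdown replicate 4; its median ranged from -0.060 to -0.028 over the libraries left out, and the cause was not tested. Fry gave immediate early and heat shock genes (median -0.12) the opposite direction. Among the named genes, 1709 values under alternatives kept direction and call, 4 turned direction and 4 became calls. Among the list results, 464 kept both, 21 lost their call, 16 gained one and 8 turned.

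Replicate numbers did not pair the libraries: same-numbered libraries had correlations of -0.04, -0.04, -0.05 and -0.16 after removal of group means. A replicate block gave 5592 genes up and 5625 down and did not change the side of the threshold of any list. In simulated data with the depth and spread of these libraries, 21 of 50 genes with the smallest simulated change were recovered; what depth alone limited was not tested.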

Other observations

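The gene families in this part were grouped by shared symbol letters and tested only after the main results were seen. Of 211 families with at least 8 measured protein-coding members, 7 passed camera at a preset correlation of 0.01, all upward, and 0 of the 7 with an estimated correlation after adjustment (7 at an unadjusted p under 0.05). In the SR splicing factors 10 of 12 genes rose and 0 fell (median 0.30, adjusted p = 0.00161, and 0.550 with an estimated correlation), with SRSF6 up by 0.87, SRSF2 by 0.81 and SRSF7 by 0.69. In the annexins, calcium-dependent membrane-binding proteins, 8 of 9 rose and 1 fell (median 0.21, adjusted p = 0.00161, and 0.550 with an estimated correlation), with ANXA3 up by 1.64, ANXA2 by 1.46 and ANXA5 by 0.56 beside ANXA1. Of 14 PSMD genes, which encode subunits of the proteasome's regulatory particle, 12 rose and 1 fell (median 0.22, adjusted p = 0.0484, and 0.550 with an estimated correlation). Of 8 CXCL chemokine genes 6 rose and 0 fell (median 0.59, adjusted p = 0.0484, and 0.619 with an estimated correlation), with CXCL5 up by 1.47 and CXCL14 by 1.34. The other 3 families were the NOP, MCM and DHX genes, with medians of 0.54, 0.27 and 0.25. Many NOP and MCM genes are also members of the ribosome biogenesis and DNA replication lists, so these families partly repeat those results. With library totals the medians of the SR factors, annexins, PSMD and CXCL genes were 0.19, 0.099, 0.11 and 0.48, so none of these 4 turned, although among members that rose PSMD1 became -0.019 and PSMD4 -0.021. The annexin and PSMD medians lay below those of the reference genes (0.24, and 0.13 with library totals). Median rises of that size are not set apart from genes of even expression.

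All 7 measured metallothionein genes, a group chosen after their values were seen, fell, by log2 fold changes from -3.17 to -1.07, and their changes were negative with library totals as well. Processed pseudogenes counted 169 up and 62 down of 1065, whereas lincRNA genes counted 125 up and 334 down of 727 and antisense genes 136 up and 296 down of 816.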
